A study of Karenia brevis with 15 samples.

How the data were processed

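Karenia brevis is a marine dinoflagellate, a single-celled alga that forms toxic blooms. Cultures of the Wilson isolate were grown in bottles and harvested after 4, 6, 10, 14 or 18 days, and the labels place days 4 and 6 in logarithmic and days 10, 14 and 18 in stationary phase. Total RNA of 3 separate cultures per day was amplified, labelled with Cy3 and hybridised to 1-colour Agilent arrays, 1 culture per array and 15 arrays in all, per the labels. Each bottle was harvested once, so the days hold different cultures.

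The authors deposited scanner output made with Agilent Feature Extraction 9.5.3.1, per the file headers and the submitters' processing notes. Its processed signal is an intensity on a linear scale, with background subtracted and spatial trends removed within the array and no scaling between arrays, per the file headers. The mean and local background intensity of each spot were also deposited. The deposited value table of the series held the same processed intensity: the largest relative difference was 4.7e-06, so its scale is linear, it is not centred and its direction is that of the signal. Its column medians equalled those of the scanner values: 761, 786 and 745 for replicates 1, 2 and 3 of day 4, 556, 434 and 930 for day 6, 550.2, 585 and 675 for day 10, 302, 292 and 455 for day 14 and 437, 357 and 597 for day 18. As an alternative setting it therefore could move nothing.

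The array carried 10263 probes of 60 bases that are not controls, each for a separate contig. Product names come from the deposited descriptions, which are shortened texts of protein similarity hits, mostly in other organisms, with no score. A name here means "described as similar to" and no more. Of the 10263 probes, 4648 had a description that named a product by the rule used here. No genome was used here, so no coordinates are given.

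Signals were taken as log2 of the processed intensity minus each array's 75th percentile over the non-control probes. Spike-in levels were means over the 7 of 10 spike-in control probes that were well above background on all arrays. Spots marked by the scanner software as non-uniform or population outliers were left out; 201 were on day 4 replicate 1 and at most 5 on any other array. Probes well above background on every array of at least 1 day were kept, which left 10053. All 15 arrays entered one limma 3.58.1 fit (lmFit and eBayes, R 4.3.3) with day as the only factor. Stationary minus logarithmic was the mean of 3 day means minus the mean of 2 day means. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15. P values were adjusted by the Benjamini-Hochberg method, and a probe was called at adjusted p under 0.05. Rises and falls of at least 2-fold were also counted.

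The 26 gene lists were patterns matched to the descriptions and fixed before the data were examined. They were tested with camera at a preset inter-gene correlation of 0.01, missing values being filled with the probe's mean, and again with an estimated correlation. Adjustment was over the 26 lists of a comparison. The patterns also matched some organism names and some unrelated proteins, and a curated version without these was added after seeing the data. Percentiles against random lists used 10000 lists of the same size matched on mean level; they treat probes as independent.

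The genes named were set by a rule fixed before the data were examined. For stationary minus logarithmic these were the 12 largest rises and 12 largest falls among called probes whose description names a product and whose stationary arrays all lay on one side of all logarithmic arrays, 1 probe per product name. To these were added up to 4 members with the smallest p of 9 set lists and of any called list, and, for each other pair of days, up to 5 rises and 5 falls among called probes.

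Alternatives were normexp background correction with offset 50, quantile normalization, median centring, no filter, a stricter filter, outlier spots kept, the value table, slide as a block, the replicate number as a block, only the arrays compared, an intensity trend with robust variance, array weights, and each array left out in turn. Added after seeing the data were fits within each slide, without day 14, spike-in scaling, curated lists, the light harvesting list without a probe with a transfer RNA-like stretch, and list tests on the other pairs of days. The arrays lay on 2 slides, each scanned separately: slide 1 held the 3 day 4 arrays and replicate 3 of every later day, slide 2 the other 8 arrays.

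The fit was tested on simulated data with 200 changed probes among 10053. For stationary minus logarithmic it recovered 52% of changes of 0.5, 93.5% of changes of 1 and 100% of changes of 2 on the log2 scale. For day 18 minus day 10, with 3 arrays a day, it recovered 20.5%, 78.5% and 96.5%. The simulated noise was independent and gave each probe the same spread on every day. In the measured data day 18 varied more. Its replicate 2 lay 0.771 (root mean square log2) from the other day 18 arrays, against at most 0.375 within days 4 to 14. The recovery for day 18 minus day 10 therefore does not hold for that wider spread. Nor does that for stationary minus logarithmic, which includes the day 18 arrays. In the measured data 6497 probes were called for stationary minus logarithmic, far more than the 200 changed here, so its simulated recovery does not carry over. The number of arrays limits the precision of every value.

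Where a probe was not well above background on any array of a day, a fold is given as "at least": the brighter day's mean against the mean, over the dimmer day's arrays, of the higher of the probe's own signal and the lowest signal among probes well above background. For stationary minus logarithmic the same value stood in for the dim day, the other day means being as measured.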

Results

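Expression was measured on 15 arrays of Karenia brevis cultures, 3 for each of days 4, 6, 10, 14 and 18. Between 9687 and 10138 of the 10263 probes were well above background on an array, and the 75th percentile of the signal ranged from 1360 to 3999. Levels below are log2 signals relative to that percentile, given as mean ± SD, and changes are differences of such levels with their limma standard error. Arrays of one day correlated across probes at 0.988 to 0.998 for days 4 to 14, and at 0.960 to 0.994 for day 18. Rises and falls below are relative to the 75th percentile: spike-in control spots gained 1.30 on it between the phases, and with scaling to them 14 probes were higher and 9584 lower in stationary cultures, the median of all probes being -1.34.

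The first comparison asked how the transcript profile of ageing, stationary cultures differed from that of cultures in logarithmic growth. Of 28 probes described as light-harvesting or photosystem proteins 19 rose in stationary cultures and 1 fell. Of 48 described as pentatricopeptide repeat or organelle RNA processing proteins 25 fell and 9 rose. Over all tested probes 29.3% were called higher and 35.3% lower. Camera called the light-harvesting list (adjusted p = 0.000916) and not the pentatricopeptide list (adjusted p = 0.175). With an estimated correlation it called neither (adjusted p = 0.663 and 0.824). The probe for chlorophyll a/b-binding protein LI818 (probe 945, contig 1654), a member of the light-harvesting list by its description, was 2.33-fold higher, at -1.87 ± 0.27 (SD, n = 9) against -3.09 ± 0.17 (SD, n = 6), adjusted p = 3.84e-06. Its sequence was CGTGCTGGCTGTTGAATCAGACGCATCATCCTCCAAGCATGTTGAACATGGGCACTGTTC. The probe for a poly (ADP-ribose) polymerase family member (probe 2055, contig 2963), an enzyme class that modifies proteins with ADP-ribose, was 5.89-fold lower, at -0.97 ± 1.29 (SD, n = 9) against 1.59 ± 0.03 (SD, n = 6), adjusted p = 3.53e-05. Its sequence was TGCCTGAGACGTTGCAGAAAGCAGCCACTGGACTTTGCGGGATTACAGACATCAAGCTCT. Of 10053 probes tested, 6497 were called, 2950 higher and 3547 lower, and 819 of them changed at least 2-fold, 260 up and the remaining 68.3% down; the 2-fold count was 533 without day 18 replicate 2 and 448 with normexp background correction. In 2468 probes every stationary array lay on one side of every logarithmic array, against 0.04% of probes by chance.

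The largest rise under the naming rule was of 60S ribosomal protein L2 (probe 7089), by 2.39 ± 0.21 (SE). The probe described as photosystem II reaction center protein I (probe 1532, contig 2353) rose by 2.22 ± 0.21 (SE), 4.66-fold. Its sequence was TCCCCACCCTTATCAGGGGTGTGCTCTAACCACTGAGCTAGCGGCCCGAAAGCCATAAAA, and the reverse complement holds TAGCTCAGTGGTTAGAGC, a stretch typical of transfer RNAs, so that its description is uncertain; 1 of the 85 named probes held such a stretch. A DNA-directed DNA polymerase (probe 4126) rose by 2.17 and basic chromosomal protein HCC4 (probe 103), a DNA-binding protein of dinoflagellate chromosomes, rose by 1.81. Gamma-glutamyltranspeptidase (probe 9546), which cleaves glutathione, rose by 1.78, although 2 of the 6 logarithmic arrays were not well above background for it. A tetratricopeptide repeat protein (probe 10438) rose by 2.10, a stereocilin-like protein (probe 4907) by 2.00, a DNA-binding response regulator (probe 9750) by 1.98 and a Kelch motif protein (probe 5653) by 1.74. A homeodomain-type transcription factor (probe 10661), an aminotransferase (probe 1484) and an acetylglucosaminyltransferase of glycan synthesis (probe 4455) rose by 1.73, 1.69 and 1.68.

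The largest falls under the naming rule were of probes described as caldesmon (probe 1178, -2.59 ± 0.55, SE), the poly (ADP-ribose) polymerase member and a Shaw-related voltage-gated channel (probe 5820, -2.51). A signal transduction histidine kinase (probe 8070) fell by 2.30, a cAMP-dependent protein kinase (probe 9004) by 2.24 and a flagellar hook-associated protein (probe 4530) by 2.24. Glutamyl-tRNA reductase (probe 9956), an early enzyme of haem and chlorophyll synthesis, was at least 4.21-fold lower, all 3 day 14 arrays being not well above background for it. A membrane spanning protein (probe 7274), a flocculin-like protein (probe 1074), a paramyosin allergen (probe 148), a minor tail protein (probe 4288) and an aminopelargonate synthase (probe 5457) fell by 2.14, 2.08, 2.00, 2.00 and 1.98. The cAMP-dependent kinase was not well above background on 2 day 14 arrays, and caldesmon, the membrane spanning protein and the flocculin-like protein on 1 each. The SD among day 18 cultures was over 1 for these probes except the minor tail protein (0.97), and the day 14 arrays and day 18 replicate 2 lay apart from the rest. Leaving out the day 14 arrays gave 4462 called probes, and leaving out day 18 replicate 2 as well gave 5443.

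**Figure D1:**
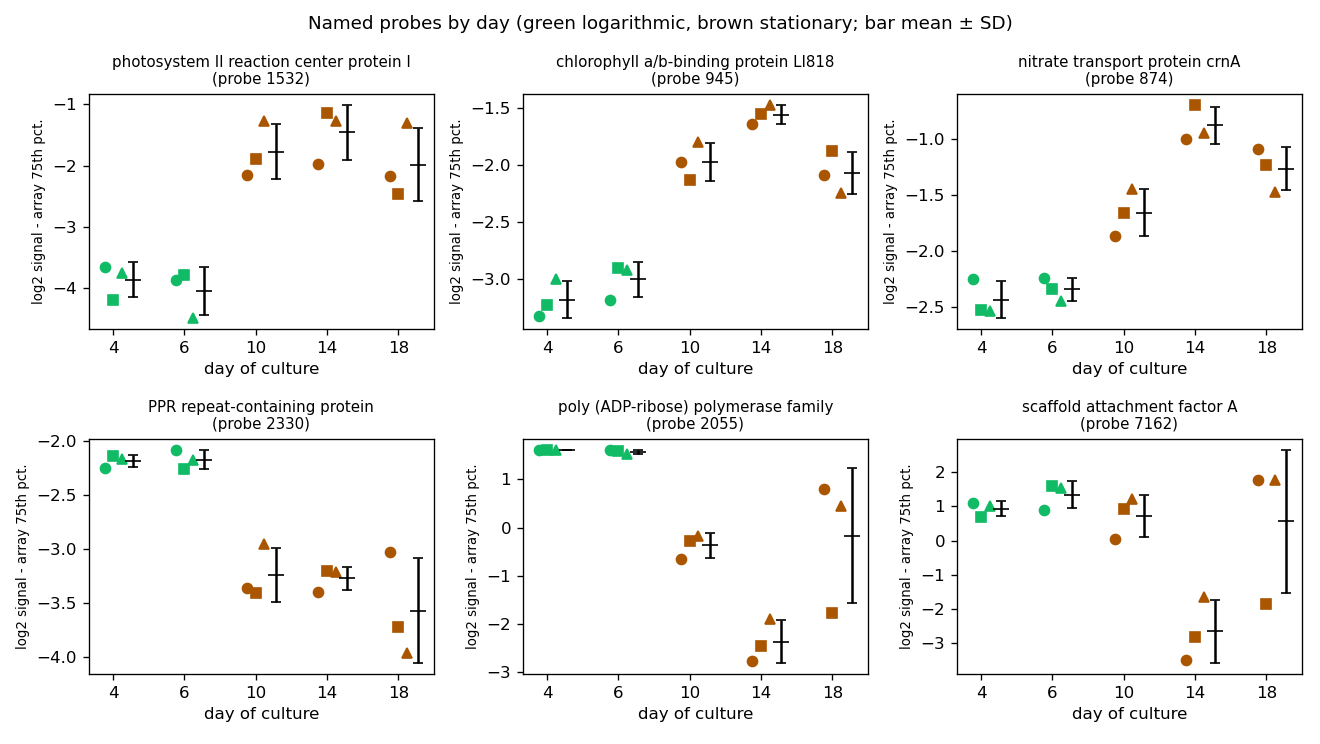
Log2 signal relative to each array's 75th percentile (vertical axis) by day of culture (horizontal axis) for 6 named probes; points are arrays (circle, square and triangle for replicates 1, 2 and 3), and bars are mean ± SD of 3 cultures. The probe described as photosystem II protein I, whose description is uncertain, lay near -3.87 and -4.05 on days 4 and 6 and at -1.77 on day 10, and scaffold attachment factor A was at -2.66 on day 14.

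The light harvesting and photosystems list was the list called by camera for stationary minus logarithmic (adjusted p = 0.000916), and not with an estimated correlation (adjusted p = 0.663). Of its 28 probes 19 rose, 1 fell and 8 were not called, with a median change of 0.43; adjusted over the list alone, 20 rose and 1 fell. The call was also lost under quantile normalization (adjusted p = 0.125, median 0.34), the range over the settings with the preset correlation being 0.000226 to 0.125. Relative to the spike-in spots the list's median was -0.87, with 1 probe higher and 25 lower. LI818 (probe 945) rose by 1.22 ± 0.08 (SE), the 12 kDa extrinsic protein of photosystem II (probe 2680) by 1.20 and a light harvesting complex protein (probe 2041) by 0.51. Without probe 1532, 18 of 27 probes rose and 1 fell, with a median of 0.42 and an adjusted p of 0.00234. The list's median was 0.40 with slide as a block, 0.29 within slide 1 and 0.42 within slide 2.

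Of 48 pentatricopeptide repeat and organelle RNA processing probes, 25 fell, 9 rose and 14 were not called, and the same counts were obtained adjusted over the list alone. Pentatricopeptide repeat proteins bind organelle RNA. The list's median was -0.35 and its camera adjusted p was 0.175, or 0.824 with an estimated correlation. Members that fell were probe 2370 (-1.28), probe 2330 (-1.18), probe 7158 (-0.79) and probe 4719 (-0.62). The median was -0.08 with normexp background correction, and with curated members the adjusted p was 0.0389, or 0.668 with an estimated correlation.

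Of 31 ribosomal protein probes 15 rose and 6 fell, with the same counts adjusted over the list alone (median 0.25, camera adjusted p = 0.245). A ribosomal protein whose shortened name begins with L2 (probe 4532) rose by 0.82 and 60S ribosomal protein L34 (probe 10024) by 1.16, whereas 30S ribosomal protein S14 (probe 10865), described from a red alga, fell by 1.25. Of 12 carbon fixation probes 7 rose and 2 fell, and adjusted over the list alone 7 rose and 3 fell (camera adjusted p = 0.245). Transketolase (probe 10442) rose by 0.99 and a ribulose bisphosphate carboxylase/oxygenase probe (10732), the carbon-fixing enzyme, by 0.47, while ribose 5-phosphate isomerase (probe 7834) fell by 0.43. The fourth named member, a fructose-2,6-bisphosphatase (probe 7033, 0.69), is not an enzyme of carbon fixation.

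Of 34 nitrogen probes 12 rose and 9 fell, and adjusted over the list alone the counts were 12 and 9 (camera adjusted p = 0.812). Nitrate transport protein crnA (probe 874) rose by 1.12 ± 0.09 (SE) and glutamine synthetase (probe 10757), which assimilates ammonium, by 0.54. Ornithine carbamoyltransferase (probe 1641) fell by 0.53, although the 3 day 10 arrays, at 0.61 to 0.64, lay at or above the logarithmic ones, at 0.46 to 0.61, and its call was lost with phase as the only factor. Probe 450, which fell by 0.55, matched the list through an organism's name. Each of the 8 phosphate probes was called, 6 up and 2 down both overall and adjusted over the list alone (camera adjusted p = 0.245). A 5-nucleotidase (probe 7971) rose by 0.95, a proton-translocating pyrophosphatase (probe 10961) by 0.63 and an inorganic pyrophosphatase (probe 3115) by 0.52, and an acid phosphatase family member (probe 3501) fell by 0.49.

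Of 30 redox probes 10 rose and 8 fell, also adjusted over the list alone (camera adjusted p = 0.793). A glutaredoxin-related protein (probe 6502) rose by 1.27, thioredoxin h (probe 1531) by 1.24, a glutathione S-transferase (probe 5756) by 0.74 and an iron/ascorbate oxidoreductase (probe 9239) by 0.45. Of 15 polyketide synthase probes, the enzyme class behind dinoflagellate polyether toxins, 4 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.885). A polyketide synthase (probe 4846) and a type I polyketide synthase (probe 8234) rose by 0.75 and 0.79, and a multifunctional polyketide-peptide synthase (probe 377) fell by 0.51. A ketoacyl-CoA thiolase (probe 4551), which is not a polyketide synthase, fell by 0.63. Of 68 cell cycle and DNA replication probes 22 rose and 24 fell, also adjusted over the list alone (camera adjusted p = 0.903). A CDC48-like ATPase (probe 1495) rose by 1.24 and a cyclin-dependent kinase-related kinase (probe 5802) by 0.76, and a DNA polymerase III delta subunit (probe 4964) fell by 0.82.

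None of the remaining lists was called, with camera adjusted p from 0.212 to 0.98. Numbers of probes that rose and fell were 10 and 5 of 17 for photosynthetic electron transport, 3 and 2 of 10 for chlorophyll and haem synthesis, 7 and 8 of 25 for glycolysis and 16 and 17 of 46 for respiration. They were 18 and 21 of 62 for translation factors, 28 and 43 of 104 for chaperones, 20 and 23 of 57 for ubiquitin and proteasome and 20 and 22 of 66 for proteases and cell death. They were 14 and 11 of 37 for chromatin, 17 and 23 of 57 for lipid metabolism, 21 and 20 of 64 for splicing and 33 and 44 of 116 for cytoskeleton and flagella. They were 57 and 80 of 191 for signalling, 4 and 4 of 11 for light perception and 69 and 73 of 222 for bacterial, viral and transposon annotations. Adjusted over the list alone, translation factors had 20 falls, lipid metabolism 18 rises, signalling 81 falls and light perception 5 rises, and the other counts did not move.

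**Figure D2:**
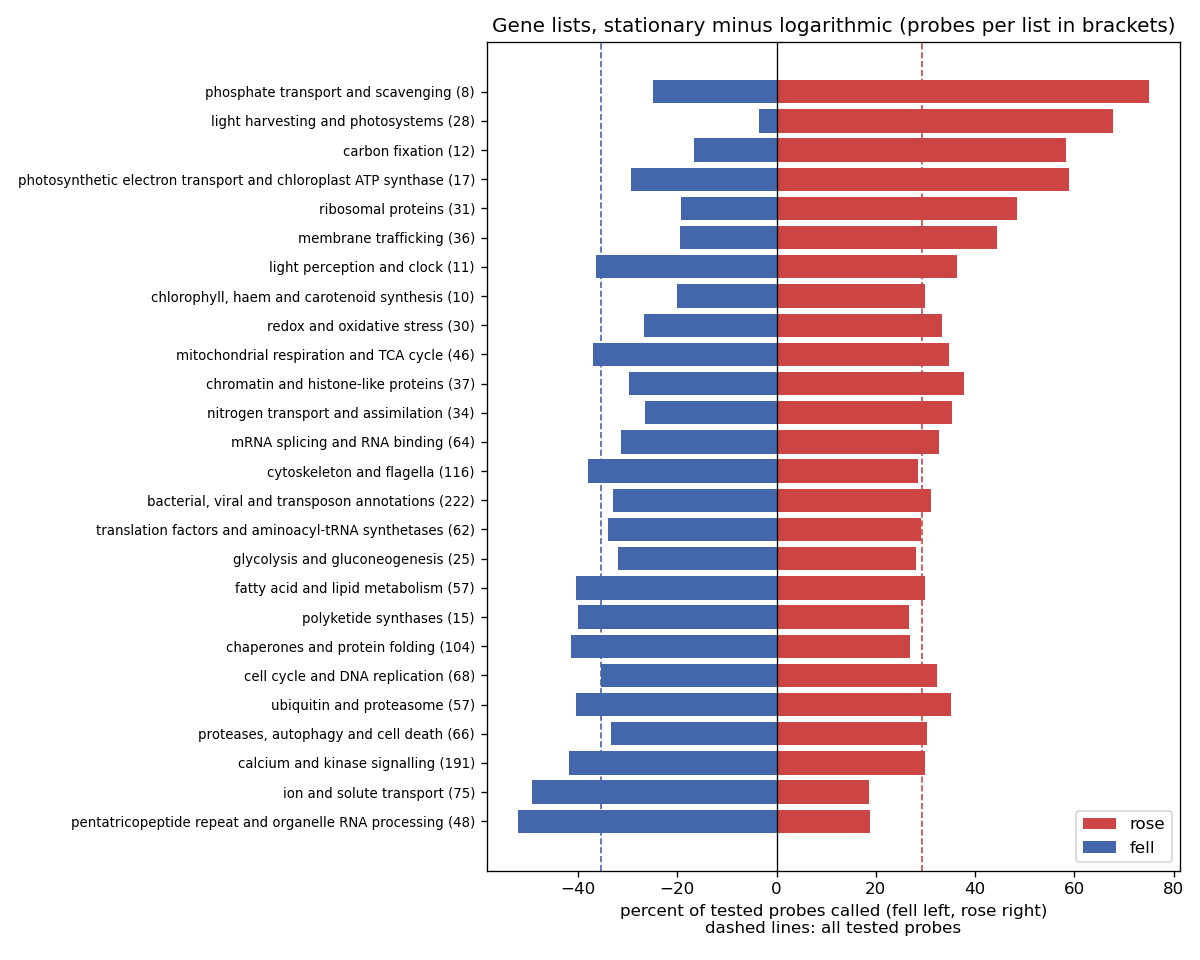
Share of each gene list's tested probes, in percent (horizontal axis), that rose (right) or fell (left) in stationary against logarithmic cultures, for the 26 lists (vertical axis, number of probes in brackets); dashed lines mark the shares over all tested probes, 29.3% higher and 35.3% lower. Of the 28 light harvesting probes 19 lay on the right and 1 on the left, whereas relative to spike-in spots 1 was higher and 25 lower.

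The split between rises and falls depended on the scaling. Of the called probes 45.4% were higher in stationary cultures, against 60.4% with median centring, which moved the median of all probes to 0.10. Called probes numbered 5895 with slide as a block, 5954 within slide 1 and 1524 among the 8 arrays of slide 2. Here and below, slide 1 held 1 array of each day after day 4, so that its calls rest on the spread of the day 4 arrays. Slide 2 held no day 4 array, so that day 6 replicates 1 and 2 were its only logarithmic arrays.

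Across all 5 days, 7181 of the 10053 probes differed by the F test at adjusted p under 0.05, and 7039 with slide as a block. Within slide 2, which held no day 4 array, 753 differed among the later days. The first principal component held 70.4% of the variance. On it the 6 logarithmic arrays lay between -35.1 and -29.6, the day 10 arrays between -13.3 and 5.94 and the day 14 arrays between 38.8 and 73.4. Day 18 replicates 1 and 3 lay at -11.4 and -3.51, and day 18 replicate 2 at 56.7.

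The next comparison was within logarithmic growth, and no named gene passed the test. Between day 6 and day 4 limma called 0 probes, with 439 at an unadjusted p under 0.05 and a lowest adjusted p of 0.2. The count was 0 with slide as a block, 2 without day 6 replicate 3 and 18 within slide 1, which held 1 day 6 array; slide 2 held no day 4 array. It was 649 with array weights, 61 with only the arrays compared and 7589, all lower, with spike-in scaling. List tests added after seeing the data called the 8 phosphate probes (median 0.14, adjusted p = 0.00865), with 0 called singly, and not with an estimated correlation (adjusted p = 0.475).

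Entry into stationary phase was compared as day 10 minus day 6. The probe described as photosystem II reaction center protein I, with its transfer RNA-like stretch, was the largest rise under the naming rule, at -1.77 ± 0.46 against -4.05 ± 0.39 (SD, n = 3 each), 4.85-fold. The tetratricopeptide repeat protein (probe 10438), 60S ribosomal protein L2, a ribosomal protein S14 (probe 9473) and the DNA polymerase (probe 4126) rose by 1.69, 1.67, 1.42 and 1.40. The other S14 probe, 30S ribosomal protein S14 (probe 10865), was lower instead, at -2.66 to -2.31 on day 10 against -1.45 to -1.27 on day 6. The poly (ADP-ribose) polymerase member fell by 1.94, a translation initiation factor 2 (probe 5600) by 1.62, the membrane spanning protein by 1.61, a protein similar to fatso (probe 3795) by 1.41 and an outer membrane receptor (probe 7343), not well above background on 1 day 6 array, by 1.36. The receptor's call was lost under 16 of 26 other settings, slide as a block and 12 of the 15 left-out arrays among them, and without day 6 replicate 2 its change was -0.74. Of the other 9 probes named here, 8 lost their call without day 6 replicate 1, 7 without day 6 replicate 3, 7 without day 10 replicate 2, 6 without day 10 replicate 1, 4 without day 6 replicate 2 and 1 without day 10 replicate 3, and probe 1532 was called under each of 27 other settings. In the added list tests the pentatricopeptide repeat list was lower (15 of 48 fell, 1 rose, median -0.27, adjusted p = 0.000901) and the light harvesting list higher (5 of 28 rose, 0 fell, median 0.27, adjusted p = 0.00507). Neither call held with an estimated correlation (adjusted p = 0.541 and 0.642). Adjusted over the list alone 21 fell and 1 rose in the former, and 9 rose and 1 fell in the latter. Quantile normalization ended the light harvesting call (adjusted p = 0.0823); without probe 1532 that list's adjusted p was 0.0189. Pentatricopeptide and light harvesting medians were -0.27 and 0.27 with slide as a block (adjusted p = 0.00172 and 0.00688), -0.21 and 0.25 within slide 1 (0.246 and 0.18) and -0.42 and 0.32 within slide 2 (0.000208 and 0.00565), and -0.82 and -0.28 relative to the spike-in spots. In all 1106 probes were called, 537 higher and 569 lower; of these 48.6% were higher, against 71.9% with median centring and 58.8% with quantile normalization. Called probes numbered 1306 with slide as a block (668 higher, 638 lower), 723 within slide 1 (368 higher, 355 lower), 0 within slide 2 with 2 arrays a day, 4967 with array weights, 3316 with only the arrays compared and 3 with spike-in scaling, which moved the median of all probes to -0.58. Without day 6 replicates 1, 2 or 3 the count was 176, 336 or 223, without day 10 replicates 1 or 2 259 or 208, and without day 18 replicate 2 3003.

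From day 10 to day 14 a set of transcripts fell steeply. Asparagine-rich protein (probe 8358) was at least 7.22-fold lower, being not well above background on any day 14 array (adjusted p = 0.00236), with the call lost under normexp background correction. Scaffold attachment factor A (probe 7162), named for a DNA- and RNA-binding nuclear protein, fell by 3.39, an agarase (probe 9791) by 3.33, the flocculin-like protein by 3.20 and caldesmon by 3.16, the last 2 being not well above background on 1 day 14 array each; the flocculin-like probe's change was -2.37 without day 14 replicate 1 and -3.81 without day 14 replicate 3. A 26S proteasome ATPase (probe 3961) rose by 1.78, a calcium-dependent protein kinase (probe 10923) by 1.73, a connective tissue growth factor-like protein (probe 6504) by 1.63, a mucolipin-like protein (probe 2968) by 1.56 and a ubiquitin-ribosomal protein S27a fusion (probe 2174) by 1.55; the call of probe 6504 was lost under 12 of 26 other settings, each of them except 2 leaving out an array. Leaving out day 14 replicate 1 also ended the calls of probes 2174, 3961 and 2968, day 10 replicates 2 or 3 those of probes 2174 and 3961, and day 14 replicate 2 that of probe 2174. In all 4735 probes were called, 2605 higher and 2130 lower, but of the 1063 that changed at least 2-fold 859 were lower. Without day 14 replicate 1 the 2-fold count was 613, 532 of them lower, and with normexp background correction 616, 469 of them lower. No list was called (lowest adjusted p = 0.121). Of the called probes 55.0% were higher, against 69.8% with normexp background correction, which moved the median of all probes to 0.22, and spike-in scaling left 16 higher and 1342 lower with that median at -0.40. With slide as a block 4938 were called. Within slide 1, where 1 array of each day was compared and the spread came from the day 4 arrays alone, 1739 were higher and 2172 lower of 3911 called, and within slide 2, with 2 arrays a day, 180 and 341 of 521, the median of all probes being 0.01 and 0.11. With each array's signal level as a covariate, which differed between these days, 425 were called. Called probes numbered 2538, 3111 and 3126 without day 14 replicate 1, day 10 replicate 2 and day 10 replicate 3.

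From day 14 to day 18 most of the larger changes were rises. Asparagine-rich protein was at least 5.14-fold higher (adjusted p = 0.00547), its call being lost with normexp background correction, and at least 3.40-fold, 11.3-fold and 3.52-fold without day 18 replicates 1, 2 and 3. Scaffold attachment factor A rose by 3.23, an olfactory receptor-like protein (probe 5928) by 2.79, a G protein-coupled receptor (probe 5929) by 2.78 and an interferon regulatory factor-like protein (probe 3963) by 2.75. These 4 means join day 18 cultures that lay apart, since probe 7162 was at 1.78, -1.85 and 1.77 in replicates 1, 2 and 3, and the 4 changes were 4.44, 3.91, 3.96 and 4.08 without replicate 2. Without replicates 1 or 3 probe 7162 was higher by 2.63 either way, probe 3963 by 2.09 or 2.08, no longer called, and probe 5929, not called without either, by 2.15 without replicate 3. Calls were also lost for probes 3963, 5929 and 7089 without day 14 replicate 1, for probes 3963 and 7089 without day 14 replicate 2 and for probe 7089 without day 18 replicate 1. Pentatricopeptide repeat probe 5601 fell by 1.32, a CDC48-interacting protein (probe 2571) by 1.07, a pre-acrosome protein-like probe (9240) and a dermal glycoprotein-like probe (5325) by 1.02 each, and 60S ribosomal protein L2 by 0.98. In all 3395 probes were called, 1400 higher and 1995 lower, and of 553 with at least a 2-fold change 540 were higher. The 2-fold count was 253 without day 14 replicate 1, 299, 1204 and 292 without day 18 replicates 1, 2 and 3, 293 with normexp background correction and 1106 with array weights. Called probes numbered 3756 with slide as a block, 4221 within slide 1 and 83 within slide 2 (78 of them higher), 6098 with array weights, 0 with only the 6 arrays compared and 4 with spike-in scaling. Without day 14 replicates 1 or 2 the count was 1727 or 1994, and without day 18 replicates 1, 2 or 3 it was 2204, 6000 or 1836. No list was called (lowest adjusted p = 0.223).

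**Figure D3:**
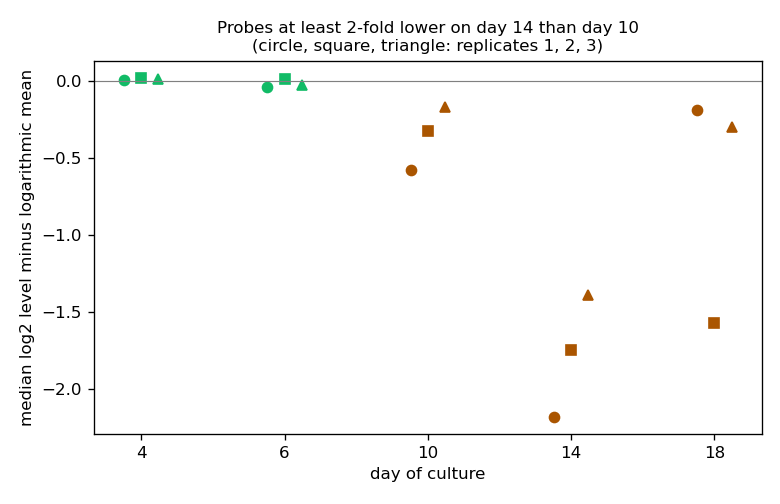
Median log2 level, relative to the mean of the logarithmic cultures (vertical axis), of the 859 probes at least 2-fold lower on day 14 than on day 10, by day of culture (horizontal axis); each point is an array. The set would hold 532 probes without day 14 replicate 1; day 14 arrays lay between -2.18 and -1.39 by selection, and day 18 replicate 2 at -1.57 while replicates 1 and 3 lay at -0.19 and -0.30.

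Late stationary phase was compared as day 18 minus day 10. Chloroplast phosphoglycerate kinase (probe 1623), a Calvin cycle enzyme, was higher by 1.53 ± 0.22 (SE), at -5.10 ± 0.38 against -6.64 ± 0.21 (SD, n = 3 each). On day 4, in logarithmic phase, it was at -5.03, -5.77 and -5.78 in replicates 1, 2 and 3, so the higher level was not particular to day 18. A sphingomyelinase D-like protein (probe 8016) rose by 1.78, and a leucine-rich repeat protein (probe 5666), an amyloid-like protein (probe 6338) and a probe described as N-myristoyl-related (10258) by 1.54, 1.54 and 1.52. The sphingomyelinase-like probe was at -4.92, -3.24 and -5.47 in day 18 replicates 1, 2 and 3, and its change was 1.12 without replicate 2. Among day 18 arrays, probes 5666, 6338 and 10258 were also highest in replicate 2, at 4.21, 1.33 and 1.23. The higher of replicates 1 and 3 lay at 3.08, -0.23 and -0.21 for them. For probes 5666, 6338 and 10258 every day 6 array lay above every day 10 array. A level above that of day 10 was thus not particular to day 18 for them. A cysteine-rich protein (probe 9900) fell by 1.36, the motor proteins KCBP-like kinesin (probe 4909) and kinesin family member 14 (probe 3911) by 1.20 and 1.11, an elongation factor-2 kinase (probe 5346) by 1.07 and pentatricopeptide repeat probe 5601 by 1.06. Of 27 other settings, 20 ended the call of probe 10258, 16 that of probe 3911, 13 that of probe 6338 and 12 that of probe 8016, leaving out any 1 day 10 array among them for each. Leaving out any 1 day 10 array also ended the calls of probes 5346, 5601, 5666 and 9900, and leaving out day 18 replicate 3 those of the first 3. The calls of probes 1623 and 4909 were lost with normexp background correction, and all 10 with only the 6 arrays compared. In all 381 probes were called, 164 higher and 217 lower, but of the 59 that changed at least 2-fold 45 were higher. That 2-fold count was 278 without day 18 replicate 1, 23 without day 18 replicate 3, 17, 11 and 19 without day 10 replicates 1, 2 and 3, and 29 to 36 without any 1 array of days 4 and 6 or day 14 replicate 2; without day 10 replicates 1 or 2 more were lower, 10 and 6, than higher, 7 and 5. It was 20 with normexp, 31 with replicate as a block, 132 with array weights and 0 with only the 6 arrays. No list was called (lowest adjusted p = 0.651, or 0.918 with an estimated correlation). Called probes numbered 409 with slide as a block, 1022 within slide 1 (294 higher, 728 lower), 0 within slide 2, 214 with normexp, 1366 with array weights, 0 with only the 6 arrays compared and 0 with spike-in scaling, which moved the median of all probes to -0.45. Leaving out 1 array moved the count by over 1.5 times for every array except day 14 replicates 1 and 3, to 1184 and 838 without day 18 replicates 1 and 2, to 98 without day 18 replicate 3, to 71, 49 and 87 without day 10 replicates 1, 2 and 3, and to 166 to 225 without the others.

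**Figure D4:**
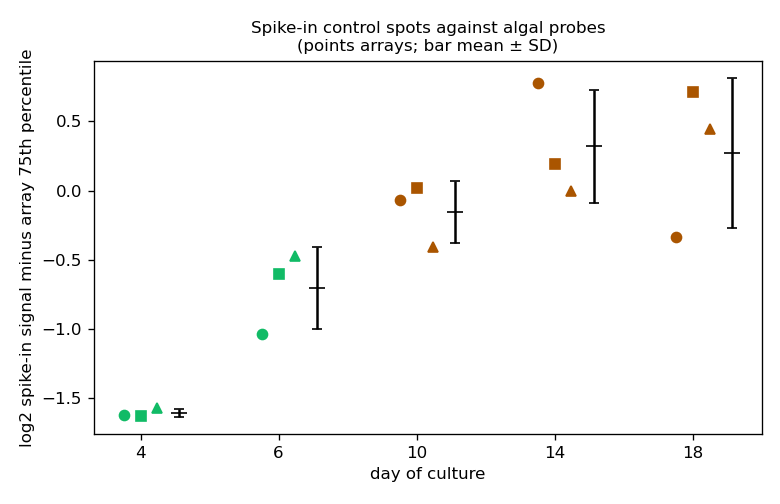
Mean log2 signal of 7 spike-in control probes minus the array's 75th percentile (vertical axis) by day of culture (horizontal axis); points are arrays and bars mean ± SD of 3 cultures. Day 4 lay at -1.60 ± 0.03 and day 14 at 0.32 ± 0.41.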

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

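The tests of slide and labelling for the spike-ins and of a wrong label, and the values with spike-in scaling, within slides and with curated members, were chosen after the results had been seen.

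Spike-in control spots, RNA added by the laboratory and left out of the comparisons except as an added scaling, were higher relative to the algal probes by 1.30 on the log2 scale in stationary than in logarithmic arrays. Against day 4 they were higher by 0.90, 1.45, 1.92 and 1.87 on days 6, 10, 14 and 18, that is 1.87-fold, 2.73-fold, 3.80-fold and 3.67-fold. The tables argue against the slide, since within slide 1 the lowest later array lay 1.10 above the highest day 4 array. The spike-in signal itself was 0.853 higher in stationary arrays. That value decides nothing about dimmer labelling of whole arrays, which would lower spike-in and algal signals alike and leave their difference unmoved. The amount of spike-in per sample is not given in the sources used here, so a change in that amount and a lower share of messenger RNA in cells of older cultures, age being a difference the design names, both stay open and untested. A day-dependent fall of most algal transcripts may therefore lie under changes reported relative to the 75th percentile, with 9584 probes lower in stationary cultures under spike-in scaling. Day 18 minus day 14 is apart from this. There the spike-in spots lay at 0.27 against 0.32, and the median of all probes under spike-in scaling was -0.02.

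The day 14 arrays and day 18 replicate 2 lay apart from the other arrays on the first principal component. Removing each array's trend on probe GC gave 4502 calls for day 14 minus day 10, against 4735 before, which argues against GC content. Day 18 replicate 2 lay 0.483 (root mean square log2) from pairs of day 14 arrays. That was beyond the 0.375 of the farthest array of days 4 to 14 from its own day. Day 18 replicate 2 lay farther, 0.771, from the other day 18 arrays. As 3 day 14 cultures cannot bound how far another would lie, these distances cannot decide whether it was a day 14 culture under a wrong label. With the array's signal level as a covariate the calls fell to 425, which met the criterion set in advance for signal level as the cause. That criterion was set aside after the result was seen: over the 4735 probes 75.1% of the change was kept at the median, with 100% of signs the same, while the median standard error rose from 0.166 to 0.211 with signal level differing between the days by -0.76, so signal level and day cannot be told apart here. A wrong label stays open, as do RNA quality and cultures ageing at different rates, which were not tested.

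The light harvesting list was higher in stationary arrays. Its median of 0.43 lay at the 99.68th percentile of random lists matched on mean level, whose median was 0.11. Those random lists treat probes as independent, and lists that were not called lay nearly as far out, electron transport at 99.66 and ribosomal proteins at 99.63. The percentile thus cannot decide whether the general rise of bright probes was the whole cause. With curated members the list's camera adjusted p was 0.000767, with 19 of 26 probes called higher and 1 lower. Curation went by description text and took out only probes that were not called, so it cannot decide whether the kept descriptions are right. Quantile normalization ended the call, the median going from 0.43 to 0.34, and 50 of 100 draws of the day labels called at least 1 list, with up to 3 called, so chance cannot be excluded for a count of 1 list. Correlation between the list's probes may account for this, as no list was called with an estimated correlation (0 lists).

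Other groupings of the same arrays were counted for each result. Of 100 draws of the day labels 1, the real one, gave as many probes for stationary minus logarithmic (6497, highest other 6039) and 1 for any difference among days (7181, highest other 4065). That share is the smallest that 100 draws can give. The draw with 6039 calls set 6 stationary arrays, the 3 of day 14 and day 18 replicate 2 among them, against the other 9, which held all 6 logarithmic arrays. A count near the real one can therefore come from setting those arrays apart, without the phase labels. For pairs of days only 10 splits exist, too few for a share under 0.05. The real counts and the highest others were 0 and 0 for day 6 minus day 4 (10 as large), 1106 and 0 for day 10 minus day 6 (1 as large), 4735 and 0 for day 14 minus day 10 (1 as large) and 381 and 37 for day 18 minus day 10 (1 as large). For day 18 minus day 14 they were 3395 and 4423 (2 as large), the higher one from the split that set day 14 replicates 1 and 2 with day 18 replicate 2. Those 3 arrays lie on slide 2 and the others on both slides; the real comparison gave 3756 with slide as a block, 4221 within slide 1 and 83 within slide 2. For the lists of day 18 minus day 10 the real count was 0 and the highest other 2 (10 as large).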

How the results depend on the processing

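Fits within a slide, without day 14, with spike-in scaling and with curated lists were added after seeing the data. The following holds for the alternatives fixed before the data were examined. The F test count and the stationary minus logarithmic count, its direction split aside, stayed within 1.5 times. Of 97 named values 0 changed sign and 62 kept their side of the threshold throughout, and 176 of 2606 values fell short of it. Named values were not scored under spike-in scaling, within slides or without day 14. Spike-in scaling left 14 probes higher and 9584 lower in stationary cultures, with the median of all probes at -1.34. The signs of the named rises are thus not shown to hold relative to the spike-in spots. The value table repeats the processed signal and tests nothing. The causes of the following changes were not tested. Fits on fewer arrays have fewer degrees of freedom, which does not account for counts that grew. The main fit pools the spread of a probe over all days. Day 18 arrays correlated at 0.960 to 0.994, against 0.988 to 0.998 within other days. Comparisons with day 18 thus borrow the smaller spread of other days, and the other comparisons carry that of day 18. Leaving out day 18 replicate 2 took day 10 minus day 6 from 1106 to 3003.

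For day 6 minus day 4 (main count 0) array weights gave 649 and only the arrays compared 61. For day 10 minus day 6 (1106) these gave 4967 and 3316, and for day 18 minus day 14 (3395) 6098 and 0. For day 18 minus day 10 (381) they gave 1366 and 0, normexp 214 and the replicate block 209. Called lists for stationary minus logarithmic (1) numbered 0 with quantile normalization, 0 with an estimated correlation, 2 with phase as the only factor, 2 with curated lists (the pentatricopeptide list at 0.0389 being the other), 3 without day 14 arrays and 3 without day 14 arrays and day 18 replicate 2.

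Within slide 1, where later days have 1 array assumed to vary like day 4, counts were 18 for day 6 minus day 4, 723 for day 10 minus day 6 and 1022 for day 18 minus day 10. Within slide 2, which held no day 4 array, counts were 1524 for stationary minus logarithmic and 753 for the F test. They were 0 for day 10 minus day 6, 521 for day 14 minus day 10, 83 for day 18 minus day 14 and 0 for day 18 minus day 10. Spike-in scaling gave 7589, 3, 1358, 4 and 0 for day 6 minus day 4, day 10 minus day 6, day 14 minus day 10, day 18 minus day 14 and day 18 minus day 10. Without day 14 arrays and day 18 replicate 2, day 18 minus day 10 gave 1389.

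Leaving out 1 array gave 5925 to 6798 for stationary minus logarithmic, 6072 to 8186 for the F test, 0 to 2 for day 6 minus day 4, 176 to 3003 for day 10 minus day 6, 2538 to 6043 for day 14 minus day 10, 1727 to 6000 for day 18 minus day 14 and 49 to 1184 for day 18 minus day 10. Called lists stayed at 1 and 0.

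Same-numbered arrays did not deviate together: over 30 pairs the correlation of deviations ran from -0.58 to 0.497, with 8 above 0.1, and 6 of 15 arrays correlated best with their own number. With the replicate block, stationary minus logarithmic gave 6380, the F test 6899, day 6 minus day 4 0, day 10 minus day 6 919, day 14 minus day 10 4573 and day 18 minus day 14 3257. On each array 94.4% to 98.8% of probes were well above background, yet with normexp the 2-fold counts were 448, 616, 293 and 20 for stationary minus logarithmic, day 14 minus day 10, day 18 minus day 14 and day 18 minus day 10, against 819, 1063, 553 and 59.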

Other observations

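The test of this part was chosen after the values were seen.

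Probes described as histone-like, major basic nuclear or basic chromosomal proteins, which package dinoflagellate DNA in place of most histones, were followed in stationary against logarithmic cultures. Of 10 such probes 9 rose and 1 fell, with a median change of 0.72; without 1 probe described as antisense, 8 of 9 rose (median 0.71). The chromatin list was not called (14 of 37 rose, 11 fell, adjusted p = 0.793). Basic chromosomal protein HCC4 rose by 1.81, a major basic nuclear protein (probe 13) by 1.15 and the brightest histone-like probe (probe 1) by 0.88, while another histone-like probe (probe 10471) fell by 1.05. Their median lay above all random lists matched on mean level (percentile 100), but the probes were picked because they rose, so this percentile decides nothing.

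Among lists that were not called, 37 of 75 ion and solute transport probes fell and 14 rose (median -0.29, adjusted p = 0.245), and 16 of 36 membrane trafficking probes rose and 7 fell (median 0.18, adjusted p = 0.212).

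The 859 probes at least 2-fold lower on day 14 than on day 10 (532 without day 14 replicate 1) were also followed in the day 18 arrays, which did not enter that difference but shared the fit's residual variance. Relative to the logarithmic mean their median was -0.19 and -0.30 in day 18 replicates 1 and 3 and -1.57 in day 18 replicate 2. Day 18 replicates 1 and 3 thus lay close together and replicate 2 lay apart. Across probes replicates 1 and 3 correlated at 0.994, and replicate 2 correlated with them at 0.960 and 0.964.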
